A study of Mus musculus with 9 samples.

How the data were processed

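Transcript levels were measured in 9 libraries of LJE1 cells, a mouse lung tumour line, in 3 groups of 3: a non-targeting guide (NT), p65 sg1 and p65 sg2. Per the labels' protocols, the cells were grown in DMEM with 10% fetal bovine serum, total RNA was isolated with the Quick-RNA Miniprep kit, polyA RNA was sequenced, and libraries were made with the TruSeq RNA Library Prep Kit v2, which does not mark the strand. The deposited values are FPKM with 3 decimals, made by the authors with HOMER (analyzeRepeats.pl with the mm10 RefSeq models, reads in exons, the transcripts of a gene condensed to a single row), per the file headers. Alignment was done with STAR 2.5 to mm10, per the submitters' processing notes, and the HOMER version is not given in the sources used here. The command in the file header numbers each guide one higher than the columns and labels do, while the library numbers match, so the column names were followed. The command also names further libraries that the table does not hold. The file gave 24537 genes with a RefSeq identifier, position and model length each. Of 23230 genes compared, 14382 starts equalled those of the RefSeq annotation and 10 were one base less, so positions are 1-based and are given for mm10.

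The depth of each library was recovered from the steps between FPKM values: the total was sought at which the value times the model length times the total gives whole reads. For 3056 to 3499 low genes per library, 100% of values were within 0.1 read of a whole number, where chance gives 20%, and over all levels with enough decimals the share was 95.8% to 99.9%. The recovered totals are those in the results, and 84.0% to 85.5% of them lay in gene models. A floor of 3 reads in a 2 kb model stood for 0.0558 to 0.08 FPKM, which covers counting error only. The 10 genes with most reads took 3.13% to 4.66% of the reads. Between replicates, the chi-square per degree of freedom over genes with at least 20 reads was 4.67 to 15.63, so no pair of libraries was a repeat of the same reads.

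FPKM values were used as deposited. Genes with a mean of at least 0.5 FPKM over all 9 libraries were tested (12120), and 12417 below that were left out. The values were transformed to log2(FPKM + 0.5) and fitted with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, with all libraries in a single fit with 3 group means, 6 residual degrees of freedom and a prior of 4.4. The contrasts were the mean of both guides minus NT (the pooled knockout), sg1 minus NT, sg2 minus NT and sg2 minus sg1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and called with both guides when it passed in the same direction in both guide contrasts. Rela was also compared by a two-sided exact permutation test of the 6 knockout against the 3 NT libraries. Every adjusted p for a gene in the text comes from limma. The overlap between guides was set beside the overlap of independent lists and beside 20 simulations of unchanged groups that share their NT libraries. In these, all 9 libraries were drawn around the NT means.

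The design, the alternatives, the rule for named genes and 25 gene lists with 700 entries were written before the data were examined. The lists were NF-kB target genes, NF-kB and IKK pathway components, T-cell-attracting chemokines, neutrophil-attracting chemokines and growth factors, interferon-stimulated genes, MHC class I antigen presentation, cytosolic nucleic acid sensing, immune checkpoint and co-stimulatory ligands, apoptosis regulators, p53 target genes, cell cycle genes, HDAC and NCoR co-repressor genes, alveolar and lung epithelial lineage genes, epithelial junction and keratin genes, mesenchymal transition genes, fibroblast and smooth muscle markers, leukocyte markers, endothelial markers, matrix proteinases and senescence-associated secreted factors, cholesterol synthesis genes, hypoxia and glycolysis genes, ATF4 and unfolded protein response genes, NRF2 target genes, serum response and immediate early genes, and ribosomal protein genes. Members were matched by their exact symbol. Lists overlap: 20 of the 39 tested NF-kB targets, 4 of the 6 neutrophil chemokines and 6 of the 30 p53 targets were also in another list. Lists with at least 5 tested members (22) were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists. Camera with a correlation estimated from the residuals and the rotation test fry, which does not compare a list with other genes, were alternatives.

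Genes were named by rule. For the pooled contrast these were the 10 highest and 10 lowest by log2 change among genes called in it and in the same direction with each guide, with a mean of at least 1 FPKM, leaving out symbols that start with Gm and a digit, end in Rik, or start with Mir or Snor. From each list, up to 4 tested members with the largest absolute log2 change in the pooled contrast were named. For sg2 against sg1 the 5 highest and 5 lowest called genes were taken, and for each guide the 3 highest and 3 lowest called with that guide and not with the other. Rela, Nfkb1, Nfkb2, Relb, Rel, Nfkbia, Cxcl10, Ccl5, Hdac3, Cd274 and B2m were always named. Other genes were chosen after their values were seen and are introduced as such.

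The sequence of each named gene and list member was compared with all other transcripts of GENCODE M21 by shared stretches of 50 bases on either strand, and its exons with those of other genes on both strands. Percentages of shared sequence come from this comparison. How HOMER assigned reads that match several places is not stated, so levels of genes that share much sequence are uncertain. GC content was found for 99.5% of the tested genes.

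The alternatives were pseudocounts of 0.1 and 1, no filter on low values, a minimum mean of 1 FPKM, scaling of each library by its median ratio, quantile normalization, a robust prior, weights per library, the replicate number as a block, a minimum absolute log2 change of 1, fits with only the groups of a contrast, and leaving out each library in turn. Added after the data were seen were limma voom on the recovered reads, removal of each library's trend on length and GC content (natural splines with 4 degrees of freedom each), and leaving out gene models under 200 bases.

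The fit was tested on data simulated from the real NT means and library sizes of all 24537 genes, of which 12167 passed the filter. Counting noise and the fitted spread of each gene were drawn independently between genes, without trends across a library. Of 100 genes changed by 0.5 log2, 81 were recovered in the pooled contrast, 71 for sg1 and 74 for sg2. Of 100 changed by 1 log2, 97, 96 and 96 were recovered, and 11, 14 and 3 unchanged genes were called. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.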

Results

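Transcripts were measured by RNA-seq of polyA RNA in LJE1 cells, an immortalized mouse line derived from a non-small-cell lung tumour with mutant Kras and without Lkb1 (KL). The cells carried a CRISPR guide against p65, the NF-kB subunit encoded by Rela, or a non-targeting guide (NT). The 9 libraries fell into 3 groups of 3: NT, p65 sg1 and p65 sg2. The series as a whole concerns the histone deacetylase HDAC3, repression of transcription and the lack of T cells in lung tumours driven by Kras, and these libraries address which transcripts depend on p65 in the tumour cells themselves. The total reads recovered from the deposited values were 26719000, 23156000 and 22798000 for NT replicates 1 to 3, 26355000, 18748000 and 22762000 for p65 sg1, and 22821000, 25196000 and 26886000 for p65 sg2. A single read in a gene model of 2 kb then stood for 0.0186 to 0.0267 FPKM, and between 15297 and 15814 genes were above 0 in each library. The first principal component held 36.5% of the variance and separated the NT libraries (−18.9 to −13.6) from the 6 knockout libraries (2.4 to 14.5). The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Levels are FPKM, given as mean ± SD over the 3 libraries of a group (n = 3), and fold changes are differences of log2(FPKM + 0.5), a scale that understates the change of genes with low values.

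Rela, the targeted gene (NM_009045, chromosome 19, 5637490 to 5648130 on the plus strand of mm10), fell with both guides, and by different amounts. Its level was 34.5, 36.1 and 35.3 FPKM in the NT libraries, 25.5, 24.7 and 26.4 FPKM with p65 sg1, and 8.65, 8.72 and 8.06 FPKM with p65 sg2. The group means were 35.3 ± 0.841, 25.5 ± 0.819 and 8.47 ± 0.362 FPKM, so that 72.3% of the NT level was left with sg1 and 24% with sg2. The pooled log2 change was −1.23 (SE 0.04, limma adjusted p = 3.06e-07), with −0.46 for sg1 (adjusted p = 0.000278) and −2.00 for sg2 (adjusted p = 9.08e-09). All 6 knockout libraries lay below all 3 NT libraries, and the two-sided exact permutation p was 0.0238, the smallest that the 84 possible splits can give. A frameshift need not lower a transcript, so the level checks the labels and does not measure the protein.

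Complement C3 fell from 2.98 ± 0.445 FPKM in NT to 0.0607 ± 0.0265 with sg1 and 0.082 ± 0.0372 with sg2 (log2 −2.60, SE 0.11, adjusted p = 5.53e-07). The monocyte chemoattractant Ccl2 fell from 11.3 ± 2.04 to 1.91 ± 0.671 and 2.53 ± 0.607 FPKM (log2 −2.14, adjusted p = 3.73e-05), and Cxcl1 from 14.6 ± 1.4 FPKM by 1.77 on the log2 scale (adjusted p = 7.22e-07). Nfkbia, which encodes the inhibitor IkB-alpha, went from 19.6 ± 0.503 to 9.86 ± 0.335 and 9.59 ± 0.763 FPKM. In the other direction, the cytokine-receptor-like factor Crlf1 rose from 22.7 ± 0.432 to 56.4 ± 3.46 and 53.9 ± 2.44 FPKM (log2 1.26, adjusted p = 3.06e-07), and the matrix protein Tnc from 5.11 ± 0.328 to 13.1 ± 1.58 and 12.7 ± 0.727 FPKM (log2 1.25, adjusted p = 4.23e-06).

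Of 12120 genes tested with limma on log2(FPKM + 0.5), 1893 (15.6%) passed an adjusted p of 0.05 in the pooled contrast, 942 higher and 951 lower in the knockout. Most changes were small, with a median absolute log2 change of 0.28 among them. On the log2 scale, 8 genes rose and 51 fell by at least 1. The 51 count the Ugt1a rows, which share their last exons and are a single locus, as several genes. Lgals4 and Lgals6, a single measurement, are also among them, so fewer than 51 loci fell by that much. The count of 1893 moved when single libraries were left out. It was 732 without NT replicate 1, 1160 without NT replicate 2, 1118 without NT replicate 3, 1238 without p65 sg2 replicate 2 and 3276 without p65 sg1 replicate 2. Of the 732, 726 were called in the same direction in the full fit. Such fits have fewer libraries, so a lower count need not be due to the library left out.

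The 10 genes that rose most, among those called with each guide, also included the urea transporter Slc14a1 (from 1.09 ± 0.0821 to 4.75 ± 0.401 and 2.81 ± 0.264 FPKM, log2 1.39, adjusted p = 3.23e-06), Osbp2 (1.18), the mechanosensitive channel gene Piezo2 (1.0), the imprinted noncoding RNA Peg3os (1.0), the growth-cone gene Gap43 (0.99), the Wnt antagonist Dkk2 (0.97), Moxd1 (0.97) and Fgfr1 (0.90), whose exons overlap 164 bases of the antisense gene Gm16159. Gap43 was the most abundant of these, with 32.7 ± 0.461 FPKM in NT, 68.4 ± 3.05 with sg1 and 62.2 ± 0.838 with sg2.

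Among the 10 that fell most were also the protease inhibitor Slpi (log2 −2.30), Gabrp (−2.05), the cytokine Il1a (−1.99) and the neighbouring membrane protein genes Tmem176b (−1.97) and Tmem176a (−1.96). Il1a went from 6.66 ± 0.08 to 0.90 ± 0.145 and 1.85 ± 0.272 FPKM, and 9.1% of its sequence is shared with the antisense gene Gm14023. Lgals6 (−1.80) and Lgals4 (−1.77) also fell, but the Lgals6 model (chromosome 7, 28834170 to 28841700) lies inside that of Lgals4 (28833794 to 28841703), so the same reads count for both rows and they are a single measurement. Of the other NF-kB subunits, Relb fell from 8.30 to 4.24 and 4.64 FPKM (log2 −0.84, adjusted p = 1.45e-05) and Nfkb2 fell by 0.48 (adjusted p = 2.85e-05, with 501 bases that overlap Psd on the other strand). Nfkb1 (adjusted p = 0.417) and Rel (adjusted p = 0.656) were not called.

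**Figure D1:**
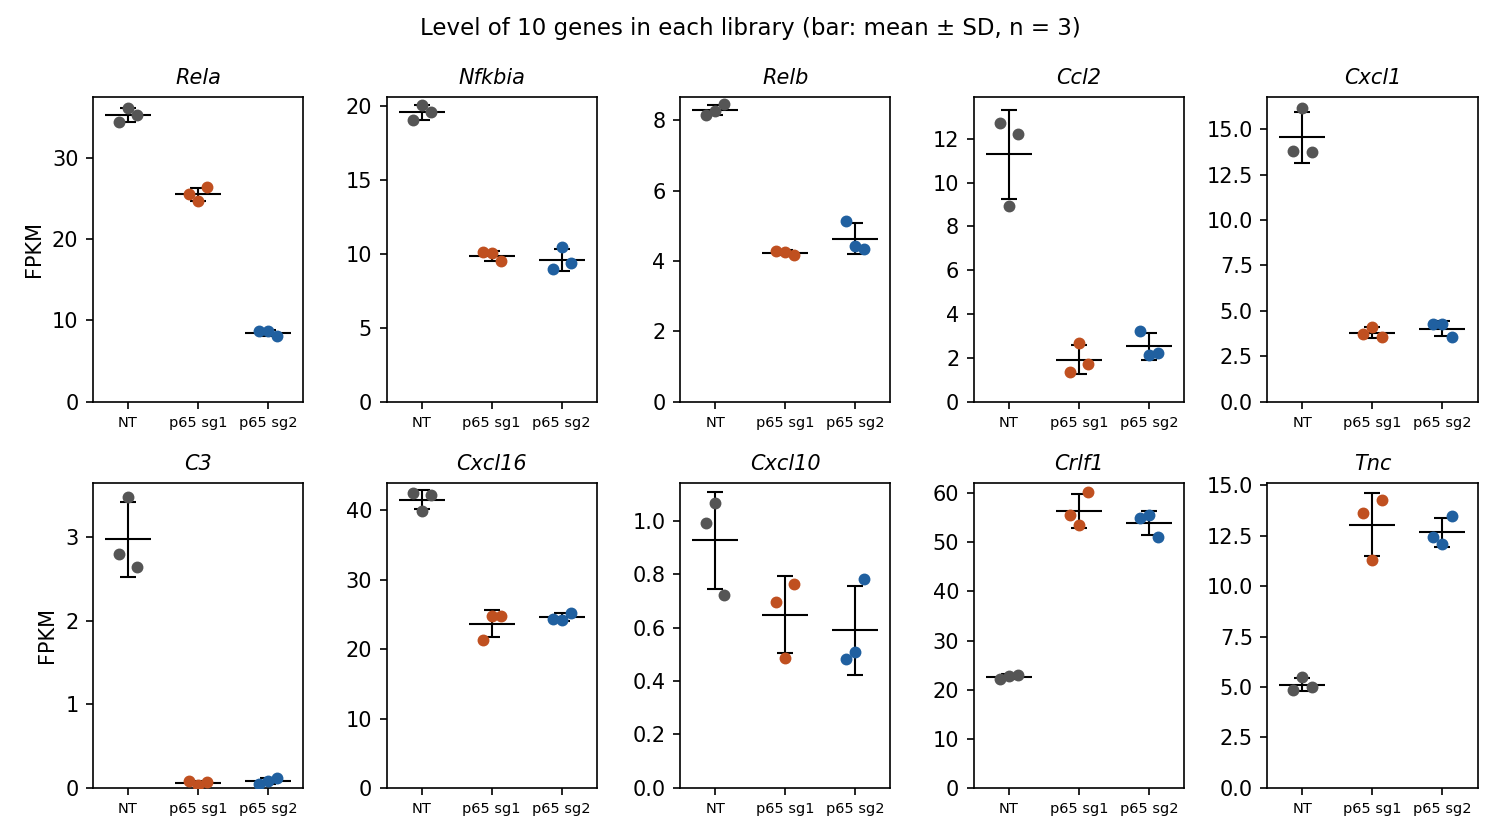
FPKM of 10 genes in each of the 9 libraries (points), grouped as NT, p65 sg1 and p65 sg2, with the group mean and SD (lines, n = 3). Rela was lower with sg2 than with sg1, whereas Nfkbia, Ccl2, C3 and Crlf1 were at similar levels with both guides.

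Genes tied to the wider question of the series were tested by name. Hdac3 was at 58.5 ± 1.3 FPKM in NT, 60.8 ± 3.11 with sg1 and 63.7 ± 0.383 with sg2 and was not called (log2 0.09, adjusted p = 0.155), although it passed without p65 sg1 replicate 2 (0.0351) and with weights per library (0.0256). The T-cell chemokine Cxcl10 was near the filter at 0.927 ± 0.181 FPKM in NT, 0.648 ± 0.143 with sg1 and 0.59 ± 0.167 with sg2, and its difference was not called (log2 −0.35, adjusted p = 0.103, 8% of its sequence shared with Art3). Ccl5 was lower, from 2.16 ± 0.522 FPKM by 0.56 on the log2 scale (adjusted p = 0.0262). That call was lost without NT replicate 1 (0.135), NT replicate 3 (0.111), p65 sg1 replicate 3 (0.0554) or p65 sg2 replicate 2 (0.0536), and with no filter on low values (0.0568). The class I light chain B2m (338 ± 6.95 FPKM in NT, log2 −0.11, adjusted p = 0.186) and Cd274, which encodes PD-L1 (0.674 FPKM in NT, log2 −0.08, adjusted p = 0.611), were not called.

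Of 25 gene lists written before the data were examined, 22 had at least 5 tested members, and 12 of them passed an adjusted p of 0.05 in the camera test with a preset correlation of 0.01, 2 toward higher and 10 toward lower values in the knockout. With a correlation estimated from the residuals, 0 of the 12 passed in camera, and 8 of the 22 had an unadjusted p under 0.05. List members introduced by the word "also" were chosen after their values were seen.

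Of 39 tested NF-kB target genes, 19 were lower and 1 higher (23 and 5 adjusted over the list alone, median log2 −0.23, camera adjusted p = 7.66e-08, adjusted p = 0.072 with an estimated correlation). C3, Ccl2, Cxcl1 and Cxcl5 (from 16.9 to 6.14 and 8.09 FPKM, log2 −1.20) led the fall, with also Vcam1 (−1.14), Bcl3 (−0.77) and Csf1 (−0.56), and the higher gene was also Ptgs2 (0.48). Of the 30 NF-kB and IKK pathway components, 4 were lower and 1 higher (4 and 2 adjusted over the list alone). The lower genes were Rela, Relb, Tlr4 (log2 −0.54) and Nfkb2, and the higher gene was also Traf6 (0.24). The NF-kB and IKK pathway list had a median log2 change of −0.03 (camera adjusted p = 0.131, adjusted p = 0.404 with an estimated correlation, 0.0435 without NT replicate 1). Because Rela is the gene targeted by the guides, part of any fall of this list is the knockout itself. The list was not tested without Rela.

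Of 6 tested neutrophil-attracting chemokines and growth factors, 4 were lower and 0 higher in limma (4 and 0 at an unadjusted p under 0.05, 4 and 0 adjusted over the list alone). The neutrophil chemokine list had a median log2 change of −0.79 (camera adjusted p = 2.44e-06, adjusted p = 0.0541 with an estimated correlation). The lower genes were Cxcl1, Cxcl5, Cxcl3 and also Ppbp (−0.34). Cxcl3 fell from 17.0 to 4.80 and 4.76 FPKM (log2 −1.74), with 6.3% of its sequence shared with Cxcl2. The difference in Csf2 was not called (−0.37, adjusted p = 0.172). Of 18 T-cell-attracting chemokines, 7 could be tested, with 3 lower and 1 higher (5 and 1 adjusted over the list alone). The T-cell chemokine list had a median log2 change of −0.40 (camera adjusted p = 0.00314, adjusted p = 0.0885 with an estimated correlation). Cxcl16 fell from 41.5 ± 1.39 to 23.6 ± 1.95 and 24.6 ± 0.541 FPKM (log2 −0.77, adjusted p = 1.09e-05), with 552 bases that overlap Zmynd15 on the other strand. The other lower members were Ccl2 (−2.14), given above as a monocyte chemoattractant, and Ccl5, whose call was lost in several fits. Cxcl10 was not called. Cxcl12 rose from 0.515 FPKM by 0.56 on the log2 scale (adjusted p = 0.00779, 0.0501 without NT replicate 1). The list was not tested without Ccl2. Cxcl9 was listed at 0 in every library, and Cxcl11 had a mean of 0.00578 FPKM, below the level of a single read in a 2 kb model, so no difference was detectable at this depth.

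Of 26 tested interferon-stimulated genes, 7 were lower and 2 higher (9 and 2 adjusted over the list alone). The interferon-stimulated list had a median log2 change of −0.11 (camera adjusted p = 0.00452, adjusted p = 0.39 with an estimated correlation, 0.0528 without NT replicate 2). Ifi27 (log2 −0.89) and Samd9l (−0.88) fell, also Stat1 (−0.35), whereas Usp18 (0.74) and also Irgm1 (0.30) rose and Irf7 (−0.55, adjusted p = 0.0557) was not called. Irf7 passed without p65 sg1 replicate 2 (0.0414) or p65 sg2 replicate 1 (0.0222), with a robust prior (0.0428), with weights per library (0.0217), with voom (0.0198) and without gene models under 200 bases (0.0408). MHC class I antigen presentation genes included 5 lower and 1 higher of 23 (7 and 1 adjusted over the list alone). The MHC class I list had a median log2 change of −0.16 (camera adjusted p = 0.000939, adjusted p = 0.104 with an estimated correlation). The peptide transporter gene Tap1 fell from 2.31 to 1.10 and 1.36 FPKM (log2 −0.71, adjusted p = 0.00257) and the proteasome gene Psmb9 by 0.54 (adjusted p = 0.022, 0.0797 without NT replicate 2, 0.0862 without NT replicate 3). These neighbours overlap by 212 bases on opposite strands, which the libraries do not tell apart. Tapbp (−0.48), also Tap2 (−0.45) and also H2-Q4 (−0.31, 39.2% of its sequence shared) fell, and the transactivator gene Nlrc5 rose from 0.717 to 1.19 and 1.16 FPKM (log2 0.46, adjusted p = 0.00682).

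For cytosolic nucleic acid sensing, 2 of 16 genes were lower and 1 higher (2 and 1 adjusted over the list alone). The nucleic acid sensing list had a median log2 change of 0.01 and a mean of −0.04, with camera pointing down (camera adjusted p = 0.89, adjusted p = 0.935 with an estimated correlation). Ikbke fell (log2 −0.65, adjusted p = 3.71e-05). Ddx58 fell by 0.32 (adjusted p = 0.0317), a call lost without NT replicate 1 (0.147), 2 (0.0924) or 3 (0.0556), without p65 sg2 replicate 2 (0.0644) or 3 (0.0624), with no filter on low values (0.0532) and with quantile normalization (0.0547). Tmem173, which encodes STING, was higher (0.18, adjusted p = 0.0312), a call lost without NT replicate 1 (0.106), NT replicate 3 (0.134), p65 sg1 replicate 1 (0.0559), p65 sg1 replicate 3 (0.0515) or p65 sg2 replicate 2 (0.0513). Ifih1 was not called (adjusted p = 0.11, 0.0278 with voom). Immune checkpoint and co-stimulatory ligands showed 2 lower and 1 higher of 13 (2 and 2 adjusted over the list alone). The checkpoint ligand list had a median log2 change of −0.03 (camera adjusted p = 0.61, adjusted p = 0.789 with an estimated correlation). Cd47, the signal against phagocytosis, fell from 46.3 to 33.1 and 30.7 FPKM (log2 −0.53, adjusted p = 0.000166) and also Pvr rose by 0.22. Nectin2 fell by 0.22 (adjusted p = 0.0208, 0.0959 without NT replicate 1, 0.0868 without NT replicate 2), and Cd40 (adjusted p = 0.0658) and Tnfsf9 (adjusted p = 0.185) were not called, although Cd40 passed without p65 sg2 replicate 2 (0.0327), with quantile normalization (0.047), with weights per library (0.0374) and after removal of length and GC trends (0.0383).

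Of 30 tested p53 target genes, 15 were lower and 0 higher in limma (17 and 1 at an unadjusted p under 0.05, 17 and 1 adjusted over the list alone). The p53 target list had a median log2 change of −0.24 (camera adjusted p = 2.85e-07, adjusted p = 0.0541 with an estimated correlation). Ephx1 fell from 9.19 to 3.48 and 4.14 FPKM (log2 −1.17, adjusted p = 1.27e-05), Ccng1 from 57.7 to 34.3 and 38.7 FPKM (−0.65, adjusted p = 0.000137) and Ddit4l by 0.68, and Tap1 belongs here too. The cell cycle inhibitor gene, also Cdkn1a, fell from 38.2 to 26.8 and 30.2 FPKM (−0.42, adjusted p = 0.000502). Apoptosis regulators held 6 lower and 0 higher genes of 28 in limma (8 and 3 at an unadjusted p under 0.05, 6 and 0 adjusted over the list alone). The apoptosis list had a median log2 change of −0.04 (camera adjusted p = 0.139, adjusted p = 0.39 with an estimated correlation). It passed with sg1 alone (median −0.10, camera adjusted p = 0.0142) and in fry (0.0344), and not with sg2 alone (median 0.02, camera adjusted p = 0.693). Casp7 (−0.35) and Bad (−0.33) fell. Birc3 fell by 0.32 (adjusted p = 0.0153), a call lost without NT replicate 1 (0.0654), 2 (0.0547) or 3 (0.054), and Bik was not called (adjusted p = 0.284).

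Cell cycle genes showed 4 lower and 2 higher of 42 (4 and 2 adjusted over the list alone). The cell cycle list had a median log2 change of −0.03 (camera adjusted p = 0.207, adjusted p = 0.404 with an estimated correlation). Kif11 fell by 0.21 (adjusted p = 0.0111, 0.0705 without NT replicate 1), and also Cdc25c, Mcm6 (both lower) and Foxm1 (higher) were called. Cdc6 was higher by 0.25 (adjusted p = 0.0215, 0.113 without NT replicate 1, 0.0729 without NT replicate 3). Nusap1 fell by 0.22 (adjusted p = 0.0327), a call lost in 7 of the fits that left out 1 library, with values from 0.0519 without NT replicate 3 to 0.163 without NT replicate 1 (0.0836 without NT replicate 2, 0.0565 and 0.0628 without p65 sg1 replicates 1 and 3, 0.0723 and 0.0671 without p65 sg2 replicates 2 and 3). It was 0.0569 with no filter on low values and 0.0515 after removal of length and GC trends. Ccne2 was not called (adjusted p = 0.173, 0.0103 without p65 sg1 replicate 2, 0.0145 with weights per library). For HDAC and NCoR co-repressor genes, 2 of 23 were higher and 0 lower in limma (7 and 1 at an unadjusted p under 0.05, 0 and 0 adjusted over the list alone). The co-repressor list had a median log2 change of 0.06 (camera adjusted p = 0.246, adjusted p = 0.404 with an estimated correlation). Ncor2 rose from 14.6 to 18 and 16.9 FPKM (0.25, adjusted p = 0.0249) and lost its call without NT replicate 2 (0.07), NT replicate 3 (0.109), p65 sg1 replicate 3 (0.0542), p65 sg2 replicate 2 (0.0568) or p65 sg2 replicate 3 (0.0531), and after removal of length and GC trends (0.0937). Hdac6 rose by 0.16 (adjusted p = 0.041) and lost its call without NT replicate 1 (0.156), NT replicate 3 (0.158), p65 sg1 replicate 1 (0.0732), p65 sg1 replicate 3 (0.0668), p65 sg2 replicate 1 (0.0724) or p65 sg2 replicate 3 (0.0796), and after removal of length and GC trends (0.0936). Hdac8 (adjusted p = 0.279) and Hdac9 (adjusted p = 0.196) were not called.

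Of 24 mesenchymal transition genes, 12 were higher and 0 lower in limma (15 and 1 at an unadjusted p under 0.05, 12 and 0 adjusted over the list alone). The mesenchymal list had a median log2 change of 0.20 (camera adjusted p = 2.63e-06, adjusted p = 0.104 with an estimated correlation). Besides Tnc, fibronectin Fn1 rose from 120 to 191 and 192 FPKM (log2 0.66, adjusted p = 0.00109), Thbs1 by 0.65 and Mmp2 by 0.61, and also Snai1 (0.38) and Zeb1 (0.22) were higher. Of 31 serum response and immediate early genes, 15 were higher and 0 lower in limma (16 and 0 at an unadjusted p under 0.05, 15 and 0 adjusted over the list alone). The serum response list had a median log2 change of 0.15 (camera adjusted p = 4.69e-08, adjusted p = 0.0947 with an estimated correlation). Fosb rose from 0.702 to 1.37 and 1.25 FPKM (log2 0.59, adjusted p = 0.00377) and Atf3 by 0.43. Klf2 rose by 0.46 (adjusted p = 0.00961, 0.0605 without NT replicate 1). Egr3 rose by 0.42 (adjusted p = 0.0248), a call lost without NT replicate 2 (0.0791), NT replicate 3 (0.103), p65 sg1 replicate 3 (0.053) or p65 sg2 replicate 3 (0.0533).

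Of 10 tested alveolar and lung epithelial lineage genes, 3 were lower and 2 higher (3 and 2 adjusted over the list alone). The lung lineage list had a median log2 change of −0.03 (camera adjusted p = 0.238, adjusted p = 0.551 with an estimated correlation). The transcription factor genes Hnf4a (from 4.57 to 2.29 and 1.99 FPKM, log2 −0.94) and Foxa2 (−0.62) and the mucin gene Muc1 (−0.32) fell, and Sox9 (from 2.16 to 3.53 and 3.86 FPKM, 0.65) and also Etv5 (0.20, 26.8% of its sequence shared) rose. Epithelial junction and keratin genes held 4 lower and 1 higher of 26 (4 and 2 adjusted over the list alone). The epithelial list had a median log2 change of −0.03 (camera adjusted p = 0.218, adjusted p = 0.714 with an estimated correlation, 0.0448 without NT replicate 3). With single guides the epithelial list was called lower with sg1 (median −0.11, camera adjusted p = 0.0083) and was not called with sg2 (median 0.03, camera adjusted p = 0.779). Krt19 fell from 1118 to 779 and 824 FPKM (−0.48, adjusted p = 0.000432) and Cldn4 rose from 115 FPKM by 0.46 (adjusted p = 4.41e-05). Tacstd2 fell by 0.36 (adjusted p = 0.0108, 0.0649 without NT replicate 1, 0.0512 without NT replicate 2), Elf3 by 0.24 (adjusted p = 0.0148, 0.0665 without NT replicate 2, 0.0661 without NT replicate 3) and also Spint2 by 0.22.

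Matrix proteinases and senescence-associated secreted factors showed 9 lower and 4 higher of 22 (9 and 5 adjusted over the list alone). The secreted factor list had a median log2 change of −0.10 (camera adjusted p = 0.0529, adjusted p = 0.448 with an estimated correlation). The list passed without NT replicate 1 (0.0231), NT replicate 3 (0.0334), p65 sg1 replicate 3 (0.0465), p65 sg2 replicate 1 (0.0252) or p65 sg2 replicate 2 (0.0406). It passed with no filter on low values (0.00253), with voom (0.0335), without gene models under 200 bases (0.0454), with sg1 alone (0.0276, beside 0.057 with sg2 alone) and in fry (0.00285), which does not compare a list with other genes. Ccl2, Il1a, Cxcl1 and Mmp13 (log2 −1.97, adjusted p = 0.00477) fell, and also Igfbp3, Igfbp7, Serpine1 and Il11 rose.

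Of 28 tested hypoxia and glycolysis genes, 12 were lower and 0 higher in limma (19 and 1 at an unadjusted p under 0.05, 19 and 0 adjusted over the list alone). The hypoxia and glycolysis list had a median log2 change of −0.25 (camera adjusted p = 1.93e-07, adjusted p = 0.39 with an estimated correlation). The lower genes were led by Bnip3 (log2 −1.22, 62.4% of its sequence shared with pseudogenes), Aldoc (−1.11), Eno2 (−0.84) and Pdk1 (−0.83, adjusted p = 0.00819, 0.052 without NT replicate 1). Only 1 of the 12, also Ldha (−0.48), was called with both guides. Cholesterol synthesis genes showed 1 lower and 1 higher of 24 (1 and 0 adjusted over the list alone). The cholesterol synthesis list had a median log2 change of −0.01 (camera adjusted p = 0.912, adjusted p = 0.975 with an estimated correlation). Pcsk9 fell by 0.47 (adjusted p = 0.0113, 0.0542 without NT replicate 1), and Hsd17b7 rose by 0.21 (adjusted p = 0.0382), a call lost without NT replicate 1 (0.155), NT replicate 3 (0.155), p65 sg1 replicate 1 (0.0532), p65 sg1 replicate 3 (0.0799), p65 sg2 replicate 2 (0.0811) or p65 sg2 replicate 3 (0.0787), and with no filter on low values (0.0604). Idi1 (adjusted p = 0.505) and Insig1 (adjusted p = 0.345) were not called.

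Of 30 ATF4 and unfolded protein response genes, 5 were lower and 1 higher (5 and 1 adjusted over the list alone). The ATF4 list had a median log2 change of −0.10 (camera adjusted p = 0.0029, adjusted p = 0.0979 with an estimated correlation). With single guides the ATF4 list was not called with sg1 (camera adjusted p = 0.0577) and was called with sg2 (0.000226). Vldlr fell from 6.45 to 2.58 and 3.92 FPKM (log2 −0.90), Cebpb by 0.44 (18.1% of its sequence shared with Tmem189), Sesn2 by 0.34, and also Herpud1 and Psat1 fell, with Atf3 the higher member. NRF2 target genes held 6 lower and 1 higher of 25 (9 and 1 adjusted over the list alone). The NRF2 list had a median log2 change of −0.12 (camera adjusted p = 0.00381, adjusted p = 0.306 with an estimated correlation). Gsta4 fell from 25.0 to 10.4 and 12.7 FPKM (−1.07, adjusted p = 0.000151), Ephx1 belongs to this list as well, Osgin1 rose by 0.39, and Prdx1 was not called (adjusted p = 0.0637, 0.00522 without p65 sg1 replicate 2, 0.00527 with weights per library, 0.0168 with voom, 0.0489 without gene models under 200 bases). Ribosomal protein genes showed 5 lower and 0 higher of 35 in limma (9 and 0 at an unadjusted p under 0.05, 5 and 0 adjusted over the list alone). The ribosomal protein list had a median log2 change of −0.09 (camera adjusted p = 0.00555, adjusted p = 0.448 with an estimated correlation, 0.0763 without NT replicate 3, 0.495 after removal of each library's length and GC trend). Rps19 fell by 0.34 (adjusted p = 0.0122, 0.0758 without NT replicate 1, 0.0541 without NT replicate 3, 53.6% of its sequence shared). Rpl3 fell by 0.32 (adjusted p = 0.0365, 85.6% of its sequence shared), a call lost in 7 of the fits that left out 1 library, with values from 0.0601 without p65 sg1 replicate 1 to 0.143 without NT replicate 1 (0.0625 and 0.123 without NT replicates 2 and 3, 0.0653 without p65 sg1 replicate 3, 0.064 and 0.0688 without p65 sg2 replicates 1 and 3). It was 0.0748 with no filter on low values and 0.0728 after removal of length and GC trends. The other called members were also Rpl23, Rpl5 and Rpl18. Rpl7 (adjusted p = 0.0764) and Rps18 (adjusted p = 0.0809) were not called, but both passed without p65 sg1 replicate 2 (0.00431 and 0.0458) and with weights per library (0.00552 and 0.0156), and Rpl7 passed with voom (0.0207).

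The 3 lists of other cell types had too few tested members for a list test. Fibroblast markers (4 of 20 tested) held S100a4, which fell from 521 to 245 and 265 FPKM (log2 −1.05, adjusted p = 0.00273, 56.3% of its sequence shared with Gm42674), and Pdgfra, which rose by 0.41 (adjusted p = 0.0294), a call lost without NT replicate 1 (0.0946), 2 (0.0646) or 3 (0.108), p65 sg1 replicate 3 (0.0635) or p65 sg2 replicate 2 (0.0556). Tagln (adjusted p = 0.453) and Col5a1 (adjusted p = 0.609) were not called. Of the leukocyte markers (3 of 24 tested), Cd14 fell from 16.6 to 9.35 and 11.5 FPKM (−0.65, adjusted p = 5.41e-05), and Coro1a (adjusted p = 0.21) and Cd68 (adjusted p = 0.911) were not called. Endothelial markers (4 of 14 tested) held Flt1, which rose by 0.38 (adjusted p = 0.0142, 0.0653 without NT replicate 3), while Eng, Esam and Egfl7 were not called, although Egfl7 passed without p65 sg1 replicate 2 (0.0414). Among the markers below the filter were also Ptprc (mean 0.0218 FPKM), Pecam1 (0.0183 FPKM) and Col1a1 (0.115 FPKM).

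**Figure D2:**
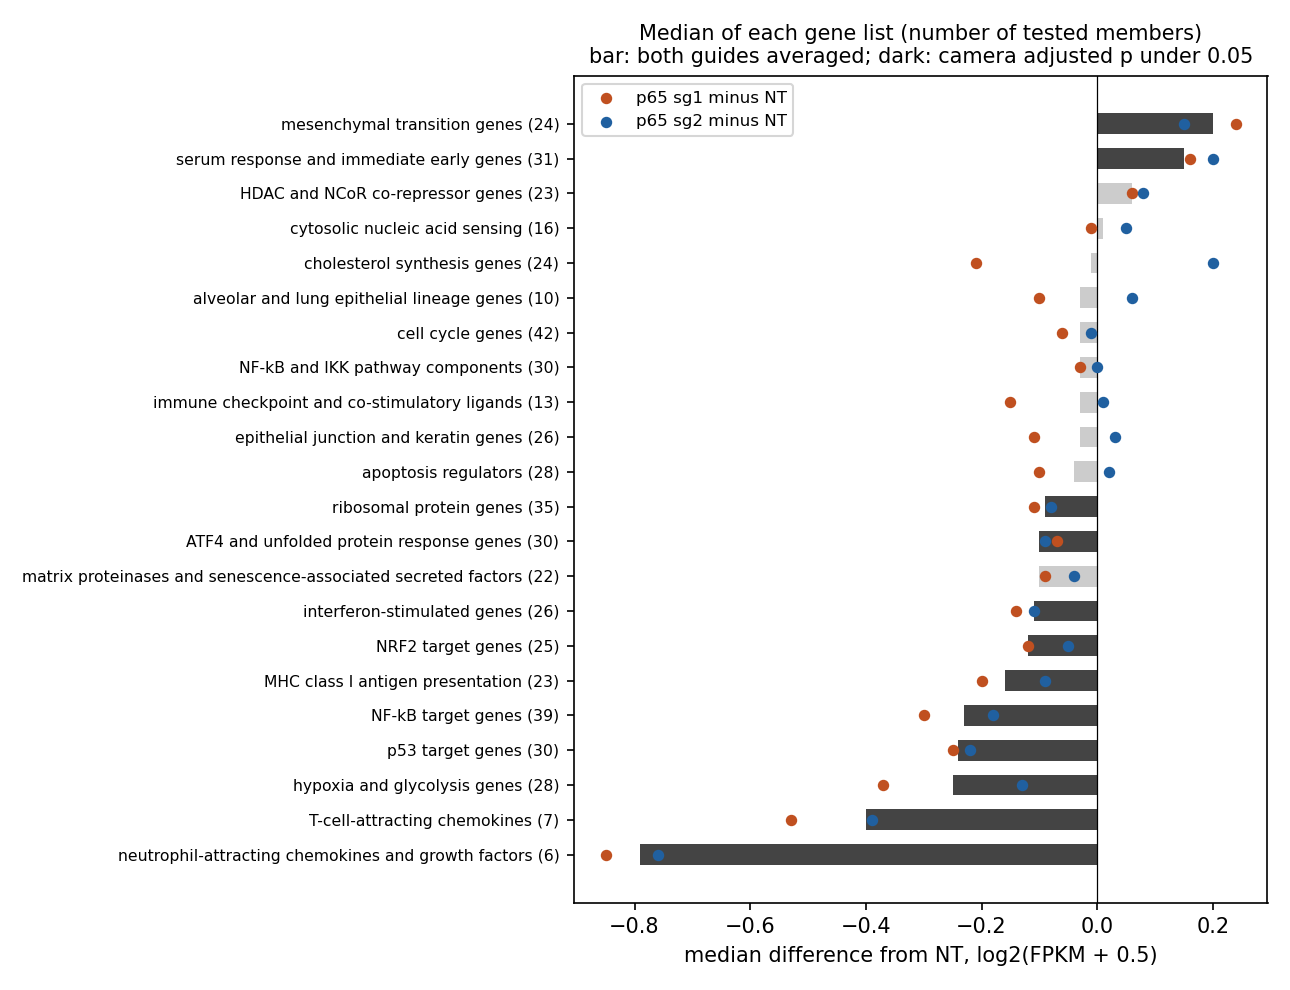
Median log2 change of the tested members of 22 gene lists in the pooled knockout against NT (bars, dark where the camera adjusted p was under 0.05) and with each guide alone (orange for sg1, blue for sg2). The cholesterol synthesis list lay below 0 with sg1 and above 0 with sg2, and the hypoxia and glycolysis list had the lower median with sg1.

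With both guides, 739 genes were called in the same direction, 361 higher and 378 lower, which was 32.7% of the 2263 genes called with either. All 20 genes listed above as the strongest changes are among them by their rule of choice. Independent lists of these sizes would share 41.3 higher and 45.8 lower genes. In 20 simulations of unchanged groups with shared NT libraries, themselves simulated, a mean of 0.05 genes and a maximum of 1 were shared. With no gene changed, hardly any gene passes the adjustment, so this count was near 0 by construction. It does not show how many genes 2 guides with unrelated changes would share through the same NT libraries. The simulated noise was independent between genes and held no trend across a library, so real unchanged groups could share more. Across genes, which are not independent replicates, the log2 changes with the 2 guides had a Pearson correlation of 0.74 where unchanged groups with shared controls gave 0.5, and a covariance of 0.0411 beside a simulated 0.00589, a difference of 0.0352. The sign was the same for 76% of genes, with 66.7% in the simulation. The 3 NT libraries are too few to be split, so part of the excess may come from the shared controls. The count was 291 without NT replicate 1, 472 without NT replicate 2, 491 without NT replicate 3, 439 without p65 sg1 replicate 3, 420 without p65 sg2 replicate 2, 431 without p65 sg2 replicate 3 and 1163 without p65 sg1 replicate 2.

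Only 5 genes were called in opposite directions, and they were named after their values were seen. Mvd, Fdps and Hmgcs1, of the mevalonate pathway, were lower with sg1 and higher with sg2. Hmgcs1 was at 61.7 FPKM in NT, 49.7 with sg1 and 76.5 with sg2, Mvd at 33.9, 26.3 and 39.8 FPKM, and Fdps, with 82.0% of its sequence shared with pseudogenes, at 32.8, 27.7 and 41.3 FPKM. The desaturase gene Scd1 (log2 −0.32 with sg1 and 0.30 with sg2) and the stress gene Ddit4 (38.9, 30.4 and 57.8 FPKM) followed the same order.

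**Figure D3:**
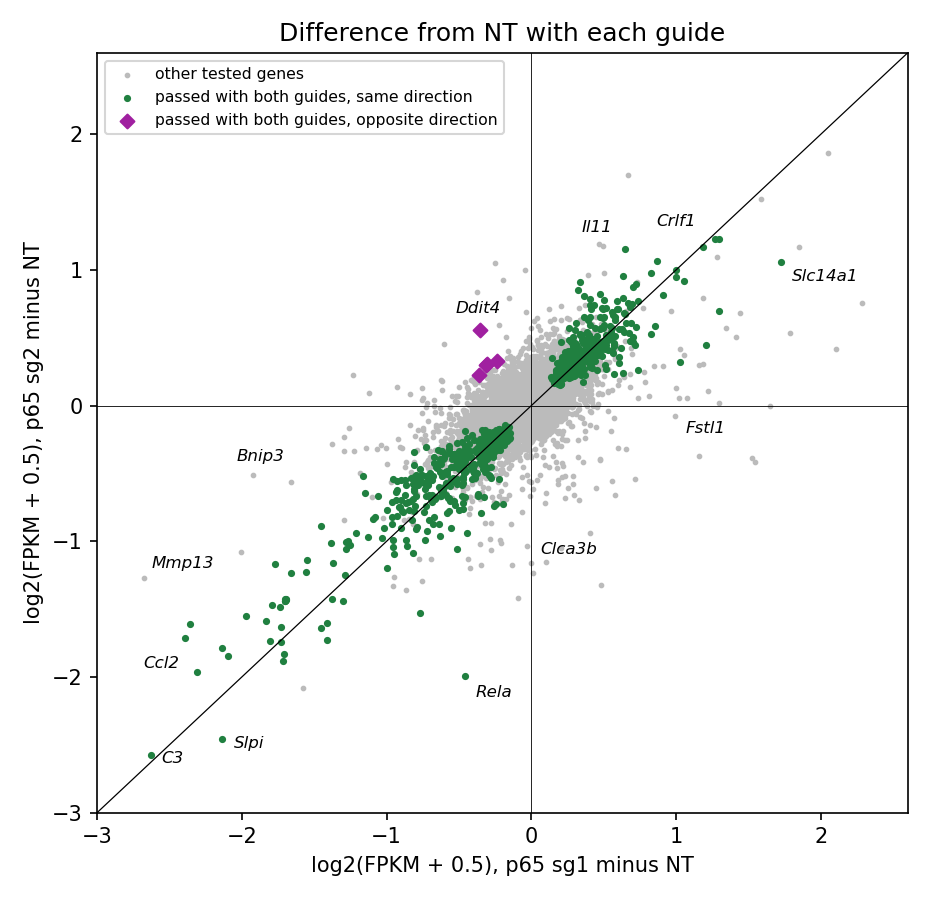
Difference of mean log2(FPKM + 0.5) from NT with p65 sg1 (x axis) and with p65 sg2 (y axis) for 12120 genes, with the line of equality. Green points are the 739 genes called in the same direction with both guides and purple diamonds the 5 called in opposite directions.

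With p65 sg1 against NT, 1794 genes passed, 719 higher and 1075 lower. This split depended on the scaling between libraries and was 971 higher and 955 lower after median-ratio scaling, 1004 and 864 after quantile normalization, and 1149 and 976 after removal of length and GC trends. Of the 1794, 1050 were not called with sg2, and 120 of those differed between the guides in the direct test. The strongest of the genes called with sg1 alone were the neuropeptide gene Vip (from 0.722 ± 0.266 to 2.08 ± 0.526 FPKM, log2 1.08, adjusted p = 0.0089), Fstl1 (from 2.01 ± 0.0807 to 4.50 ± 0.296 FPKM, 0.99, adjusted p = 2.78e-05) and Sall1 (0.81, adjusted p = 0.000316) on the higher side. On the lower side were the collagenase gene Mmp13 (from 7.52 ± 3.14 to 0.706 ± 0.28 FPKM, −2.68, adjusted p = 0.00235), the mitophagy gene Bnip3 (−1.92, adjusted p = 0.00258, 62.4% of its sequence shared) and the aldolase gene Aldoc (−1.66, adjusted p = 0.00146). Mmp13 was not called in the direct test between guides (adjusted p = 0.103). The count was 688 without NT replicate 1, 1018 without NT replicate 2, 1051 without p65 sg1 replicate 1, 747 without p65 sg1 replicate 3 and 3290 without p65 sg1 replicate 2.

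With p65 sg2 against NT, 1213 genes passed, 697 higher and 516 lower, and 469 of them were not called with sg1, of which 77 differed between the guides. The split into higher and lower genes was 575 and 607 after median-ratio scaling, 623 and 553 after quantile normalization, 734 and 690 after removal of length and GC trends, and 368 and 377 without NT replicate 3. Il11 rose from 3.12 ± 0.549 to 7.91 ± 2.37 FPKM (log2 1.19, adjusted p = 0.00362), the interferon-response protease gene Usp18 by 0.98 (adjusted p = 0.00348) and the growth arrest gene Gadd45a from 5.75 ± 0.566 to 11.7 ± 1.88 FPKM (0.96, adjusted p = 0.00104, with 238 bases that overlap E230016M11Rik on the other strand). Clca3b fell from 19 ± 2.97 to 8.97 ± 0.405 FPKM (−1.03, adjusted p = 0.000114), the cornified envelope gene Sprr2k by 0.87 (adjusted p = 0.00843) and Plac8 by 1.13 (adjusted p = 0.017, 0.0781 without NT replicate 1, 0.0677 without p65 sg2 replicate 2, 0.0631 without p65 sg2 replicate 3, 0.0596 with a robust prior). In the direct test between guides, Gadd45a (adjusted p = 0.0452) and Clca3b (adjusted p = 0.00128) differed, whereas Il11 (0.0797), Usp18 (0.144), Sprr2k (0.113) and Plac8 (0.492) were not called. The count was 501 without NT replicate 1, 745 without NT replicate 3, 636 without p65 sg2 replicate 2 and 623 without p65 sg2 replicate 3.

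The guides were also compared directly, to ask which changes depended on the guide used. Of the 12120 genes, 279 (2.3%) differed, 201 higher and 78 lower with sg2. That split was 111 and 111 after median-ratio scaling, 107 and 95 after quantile normalization, 191 and 179 after removal of length and GC trends, and 82 and 51 with no filter on low values. Rela was the gene furthest down with sg2 (log2 −1.54, adjusted p = 1.35e-07), followed by Fstl1 (−1.07, adjusted p = 0.000236), the metalloproteinase inhibitor gene Timp3 (from 42.7 ± 7.66 FPKM with sg1 to 20.5 ± 1.74 with sg2, −1.02, adjusted p = 0.00279, 36.3% of its sequence shared with other genes such as Syn3), Vip (−1.02, adjusted p = 0.0368) and Clca3b (−1.0). Higher with sg2 were 5 genes known to respond to low oxygen. Bnip3 was at 2.95 ± 0.502 FPKM with sg1 and 9.41 ± 5.11 with sg2 (1.41, SE 0.29, adjusted p = 0.0396), the lactate transporter gene Slc16a3 at 16.0 ± 2.43 and 35.6 ± 10.5 (1.10, adjusted p = 0.0229), Pdk1 at 3.72 ± 0.466 and 8.68 ± 2.36 (1.09, adjusted p = 0.021), Aldoc at 1.63 ± 0.21 and 4.26 ± 1.8 (1.10, adjusted p = 0.0419) and Stc1 at 8.98 ± 0.817 and 19.6 ± 5.07 (1.06, adjusted p = 0.0284).

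Most of these single calls between guides were lost when single libraries were left out, although the differences kept their direction. In the fits that lost the call, the log2 difference was 1.02 to 1.49 for Bnip3 and 0.87 to 1.16 for Slc16a3. Without p65 sg1 replicate 3, p65 sg2 replicate 1 and p65 sg2 replicate 3 in turn, the adjusted p was 0.149, 0.0677 and 0.112 for Bnip3, 0.104, 0.0616 and 0.0733 for Slc16a3, 0.104, 0.0789 and 0.0909 for Pdk1, 0.149, 0.101 and 0.117 for Aldoc, 0.119, 0.105 and 0.101 for Stc1, and 0.144, 0.135 and 0.134 for Vip. Without p65 sg1 replicate 1 it was 0.091 for Bnip3, 0.0601 for Slc16a3, 0.0943 for Aldoc and 0.0601 for Stc1, and without p65 sg1 replicate 2 it was 0.052 for Vip. Without NT replicate 1 it was 0.066 for Bnip3, 0.0683 for Aldoc, 0.0546 for Stc1 and 0.0505 for Vip, and without NT replicate 3 it was 0.0546 for Bnip3, 0.0503 for Aldoc and 0.059 for Vip. With no filter on low values the adjusted p of these 6 genes lay between 0.0637 for Pdk1 and 0.102 for Aldoc, with a robust prior it was 0.11 for Bnip3, 0.0807 for Aldoc, 0.0705 for Slc16a3 and 0.078 for Stc1, and after median-ratio scaling 0.0503 for Aldoc. The calls of Rela, Fstl1, Timp3 and Clca3b were kept in every fit without 1 library. The count of 279 was 125 without NT replicate 1, 183 without NT replicate 3, 147 without p65 sg1 replicate 1, 54 without p65 sg1 replicate 3, 44 without p65 sg2 replicate 1, 54 without p65 sg2 replicate 3 and 570 without p65 sg1 replicate 2.

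Among the 22 lists, 5 differed between the guides in camera with the preset correlation, and each had an adjusted p of 0.45 with an estimated correlation. Cholesterol synthesis genes were higher with sg2 (16 of 24 called, median 0.43, camera adjusted p = 5.92e-19, adjusted p = 0.45 with an estimated correlation), lower than NT with sg1 (median −0.21, camera adjusted p = 2.32e-05) and higher than NT with sg2 (0.20, camera adjusted p = 1.87e-05). Hypoxia and glycolysis genes were higher with sg2 than with sg1 (8 of 28 called, median 0.32, camera adjusted p = 9.13e-12, adjusted p = 0.45 with an estimated correlation). Smaller shifts were found for epithelial junction and keratin genes (3 of 26 called, median 0.16, camera adjusted p = 7.09e-05), apoptosis regulators (0 of 28 called in limma, 10 at an unadjusted p under 0.05, median 0.10, camera adjusted p = 0.00967, 0.0532 without p65 sg1 replicate 1) and mesenchymal transition genes (1 of 24 called, median −0.06, camera adjusted p = 0.00159), each with an adjusted p of 0.45 with an estimated correlation. The NF-kB target list was not called as different between the guides (1 of 39 genes called, camera adjusted p = 0.181), although Rela was.

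**Figure D4:**
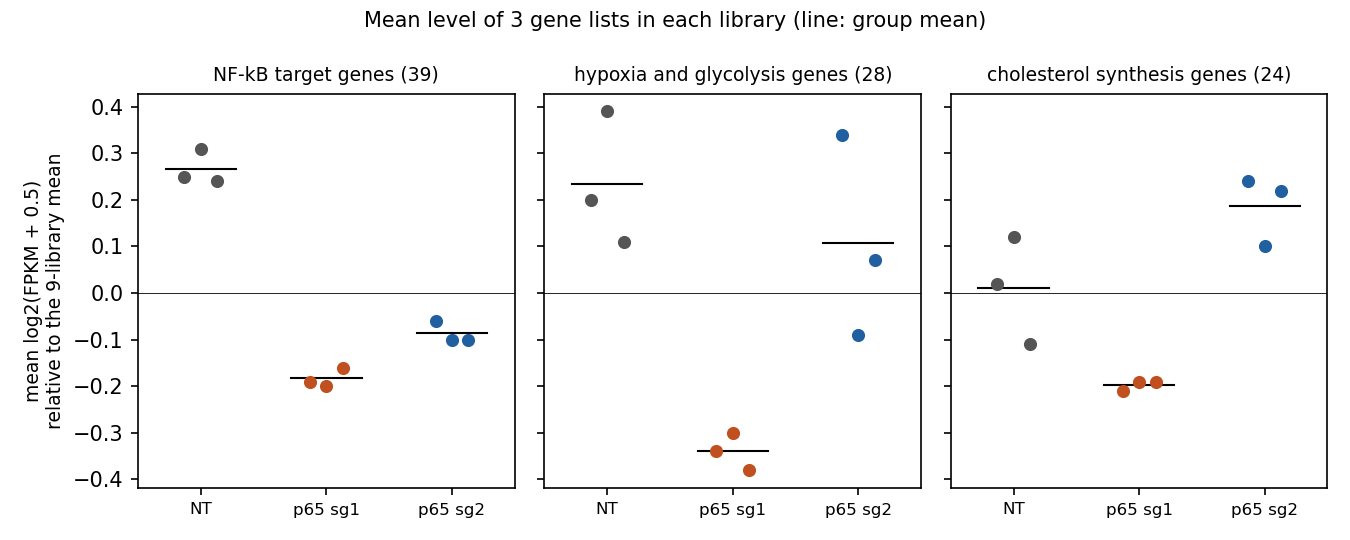
Mean log2(FPKM + 0.5) of the tested NF-kB target genes (39), hypoxia and glycolysis genes (28) and cholesterol synthesis genes (24) in each library, relative to the mean of the 9 libraries (points), with the group mean (line). The mean of the NF-kB targets was below NT in every knockout library, and the other lists separated sg1 (hypoxia −0.38 to −0.30) from sg2 (−0.09 to 0.34).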

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

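The tests of Rela (scaling, and p65 function left with sg1) and of a hypoxia state that varies within a group were chosen only after the result was seen, and the removal of length and GC trends was added after the data were seen.

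A tested difference between the effects of the guides drew attention to 279 genes. Lower with sg2 than with sg1 were Rela (log2 −1.54), Fstl1 (−1.07), Timp3 (−1.02), Vip (−1.02), Clca3b (−1.0), Sall1 (−0.74), Hdac9 (−0.73), Slc14a1 (−0.67) and Peg3os (−0.6). Higher with sg2 were Foxa2 (0.37), Insig1 (0.48), Pcsk9 (0.52), Gadd45a (0.56), Il1a (0.75), Stc1 (1.06), Pdk1 (1.09), Slc16a3 (1.1), Aldoc (1.1) and Bnip3 (1.41). Of the lists, the median difference was 0.1 for apoptosis regulators, 0.16 for epithelial junction and keratin genes, −0.06 for mesenchymal transition genes, 0.43 for cholesterol synthesis genes and 0.32 for hypoxia and glycolysis genes. A refit of the 6 knockout libraries alone called 91 genes between guides, and the highest of the other splits gave 1, but 10 splits are too few for a share under 0.05.

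The Rela transcript kept 72.3% of its NT level with sg1 and 24% with sg2. Scaling between libraries does not account for this, since the difference was −1.57 after median-ratio scaling. If sg1 left more p65 function, the NF-kB targets that fell should lie higher with sg1. The 19 of them instead lay higher with sg2 by a median of 0.15. Their library means were 2.18 with sg1, 2.29 to 2.38 with sg2 and at least 3.08 in NT. In limma, 0 of them differed between guides (7 at an unadjusted p under 0.05). These 19 were chosen by their call in the pooled contrast, which can miss targets that fell with 1 guide only. All 39 tested targets also lay higher with sg2 (median 0.1, camera adjusted p = 0.181). Cdx2 and Cdh17, chosen after their values were seen, fell more with sg2 (−0.53 and −0.49). The comparison covers NF-kB targets only, and p65 protein was not measured. Transcript decay that depends on the position of the guide site stays open as a biological explanation and was not tested, since no guide sequence was available.

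The hypoxia and glycolysis list was lower with sg1 than with sg2 in camera (adjusted p = 0.45 with an estimated correlation). A trend on transcript length or GC content as the whole cause is argued against by the median difference after its removal, 0.28 against 0.32 before (camera adjusted p = 5.28e-14). Reads shared with pseudogenes are argued against by the 15 members with under 5% of shared sequence, whose median difference was 0.37. A state that varies between libraries of the same group may be the source, though the labels do not say that these were separate cultures. The list mean differed by 0.44 between guides and ranged over 0.43 within sg2, 0.28 within NT and 0.09 within sg1. All sg1 libraries (−0.38 to −0.3) lay below all others (−0.09 to 0.39), so the variation within sg2 and NT did not reach the sg1 level. An effect of the guide itself stays open, because culture and guide cannot be separated with 3 libraries each.

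The number of genes changed in the pooled knockout could follow from trends on transcript length, because the pooled log2 change correlated with length across genes (Spearman 0.28, genes not being independent replicates). After each library's trends were removed, 84.5% of the 1883 called genes with a GC value were still called in the same direction, which argues against such trends as the whole cause.

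Other splits of the 9 libraries into groups of the same sizes were drawn. The 1893 genes of the pooled contrast were reached in 1 of 100 splits, the real one included, with a highest other of 1314. For the 739 genes shared by both guides it was also 1 of 100, with a highest other of 515. These shares argue against chance only if the libraries are independent. The labels do not say that they are, so a chance difference between cultures cannot be excluded. The splits that came closest keep the NT libraries together and mix only the guides, and the 97 splits that mix NT with knockout libraries gave at most 97 genes in the pooled contrast and 4 with both guides. For the 12 lists, chance cannot be excluded, because 12 of the 100 splits gave as many and the highest other gave 15. For sg1 (1249 genes in a refit of its 6 libraries, highest other 0) and sg2 (1537, highest other 1), the 10 splits are too few for a share under 0.05.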

How the results depend on the processing

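The fits with voom, with length and GC trends removed, and without short gene models were chosen after the data were seen.

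Of 123 results for named genes in the pooled contrast over 21 settings, 0 reversed, that is, changed sign while called before or after, and 87 kept their side of the threshold throughout, among them 67 of the 93 called. Genes that were not called, such as Stc1, B2m and Cd68, changed sign in some settings. Calls were lost for 21 genes without NT replicate 1, 12 without NT replicate 2 and 17 without NT replicate 3. The replicate block lost 10, those of Ddx58, Tmem173, Cdc6, Nusap1, Ncor2, Hdac6, Pdgfra, Hsd17b7, Egr3 and Rpl3. Of 24 results for single guides or between guides, 17 kept their call throughout and 0 reversed. The Rela change ranged from −1.25 to −1.21 without 1 library and from −1.27 to −1.2 otherwise.

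Counts of called genes moved more. Weights per library gave 3644 genes in the pooled contrast, 4240 with sg1, 2000 with sg2, 1268 between guides and 1411 with both guides, and the cause was not tested. Leaving out the library with the lowest weight (0.3) and the lowest depth, p65 sg1 replicate 2, gave 3276, 3290, 1776, 570 and 1163, and kept 1889 of the 1893 genes. This library also differed from its group in length trend. Its deviations from the gene means correlated with model length at Spearman −0.28, against 0.38 and 0.23 in p65 sg1 replicates 1 and 3. In the NT libraries the correlation was −0.33 to −0.05. Which of these traits raised the counts was not tested. Leaving out 1 library gave 732 to 3276 genes in the pooled contrast (1160 without NT replicate 2, 1118 without NT replicate 3, 1238 without p65 sg2 replicate 2), 688 to 3290 with sg1 (1018 without NT replicate 2, 1051 and 747 without p65 sg1 replicates 1 and 3), 501 to 1776 with sg2 (745 without NT replicate 3, 636 and 623 without p65 sg2 replicates 2 and 3), 44 to 570 between guides (125 and 183 without NT replicates 1 and 3, 147 and 54 without p65 sg1 replicates 1 and 3, 44 and 54 without p65 sg2 replicates 1 and 3) and 291 to 1163 with both guides (472 and 491 without NT replicates 2 and 3, 439 without p65 sg1 replicate 3, 420 and 431 without p65 sg2 replicates 2 and 3). The lowest counts came without NT replicate 1, except between guides. A fit without 1 library has fewer samples, so a lower count or a lost call need not be due to that library. A minimum log2 change of 1 left 59, 75, 58, 13 and 41 genes by its construction. Except for the 13, these counts hold the Ugt1a rows, a single locus, as several genes. Between guides, no filter gave 133 genes and a fit of only the 6 knockout libraries gave 91, and the cause was not tested. Voom on the recovered reads gave 2375 genes in the pooled contrast, 1827 of them shared, and removal of length and GC trends gave 2147, 1592 of them shared.

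The replicate number as a block gave 1144 genes in the pooled contrast (1140 shared), 980 with sg1, 692 with sg2, 69 between guides and 413 with both guides, and moved no list past the threshold. The numbers did not pair the samples: 0 of 9 pairs with the same number correlated over 0.1 (−0.34 to 0.06, other pairs −0.14 to 0.29), and 0 of 9 samples correlated best with its own number.

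Of the 12 lists, 0 passed with an estimated correlation (8 of 22 at an unadjusted p under 0.05 in camera). Of the 22 lists tested, 17 passed with fry, which asks another question. Fry added the NF-kB and IKK pathway (0.00139), apoptosis (0.0344), cell cycle (0.0431), co-repressor (0.0414), lung lineage (0.00947) and secreted factor (0.00285) lists and lost the ribosomal protein list (0.128). The NF-kB and IKK pathway list includes the targeted gene Rela and was not tested without it. With sg1 alone the apoptosis, epithelial, secreted factor and cholesterol synthesis lists were added and the ATF4 list was lost. Without 1 library, 11 to 14 of the 22 passed in camera. The cholesterol synthesis list reversed with sg2 alone, where it was higher (adjusted p = 1.87e-05, range over its alternatives 1.87e-05 to 0.99). All 5 differences of lists between guides were lost with an estimated correlation (0.45).

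Depth limits genes near the level of 3 reads, 0.0558 to 0.08 FPKM in a 2 kb model. Shared sequence and the lack of strand limit single genes, 3 libraries per group limit the spread, and the labels give no batch.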

Other observations

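The test of an intestinal and gastric gene set was chosen only after the result was seen, as were the genes named here.

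Intestinal and gastric genes were expressed in this lung tumour line, and several fell in the knockout. Cdx2 went from 34.2 FPKM in NT to 29.9 with sg1 and 20.5 with sg2 (log2 −0.46, adjusted p = 2.54e-05), Cdh17 from 94.6 to 79.3 and 56.4 FPKM (−0.50), Tspan8 from 293 to 155 and 160 FPKM (−0.92, adjusted p = 0.00512), Anxa10 from 32.6 to 16.7 and 19.7 FPKM (−0.84) and Agr2 from 1.32 to 0.0337 and 0.329 FPKM (−1.47), whereas Gpa33 rose from 8.43 to 9.46 and 12.5 FPKM (0.35, adjusted p = 0.00225). Cdx2 and Cdh17 fell more with sg2 than with sg1 (sg2 minus sg1 log2 −0.53, adjusted p = 0.000388, and −0.49, adjusted p = 0.0016). Lgals4 (adjusted p = 0.608) and Hnf4a (adjusted p = 0.326) were not called between the guides. A hypothesis from the fall of Cdx2, Cdh17, Lgals4 and Hnf4a is that p65 loss may lower an intestinal and gastric gene set. Of 53 genes of such a set other than Cdx2, Cdh17, Lgals4 and Hnf4a, 16 could be tested, with 6 lower, 1 higher and a median of −0.09 (camera p = 0.0146, p = 0.153 with an estimated correlation), which leaves the hypothesis undecided. Tspan8, Anxa10, Agr2 and Gpa33, given above, are among these 16 and are not additional to them.

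The alarmin Il33 fell from 90.8 to 47.3 and 56.0 FPKM (log2 −0.81, adjusted p = 2.94e-05), while Il23a rose from 28.8 to 41.4 and 38.6 FPKM (0.46). Bmp7 rose from 2.95 to 3.87 and 5.99 FPKM (0.63) and Bmp6 by 0.75, while Bmp4 fell by 0.49. The fall of Bmp4 was called with sg1 (−0.73, adjusted p = 0.00185) and not with sg2 (−0.26, adjusted p = 0.153). Bmp4 also differed between the guides (adjusted p = 0.0472). The Ugt1a rows fell together, as with Ugt1a1 from 3.13 to 0.616 and 0.849 FPKM (−1.56), but they share their last exons and are a single locus. Serpinb1a fell by 1.55 on the log2 scale.

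Gapdh was listed at only 2.46, 1.71 and 2.21 FPKM in NT, sg1 and sg2, and 90.4% of its sequence is shared with pseudogenes.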
